A study of Mus musculus with 2 samples.

How the data were processed

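The series holds 2 samples of splenic CD4+CD25+ T cells, 1 from PBS-treated and 1 from STAg-treated mice. The libraries were 10x Genomics single-cell libraries per the labels of the series, and the reads were processed with Cell Ranger against mm10, per the submitters' processing notes. The Cell Ranger version and the annotation are not given in the sources used here. The deposited table holds raw UMI counts per gene and cell. The values show that it had been filtered before deposit, although no source used here states how: every cell has at least 400 detected genes. Most ribosomal protein genes and T-cell receptor and immunoglobulin segments were not analysed here. The cell columns used here carry no names, so each cell's group is unknown, and no group was inferred from column order or from values. The planned comparison of STAg with PBS was therefore not made, and the table was treated as 1 pooled sample, as laid down for this case before the data were examined.

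Cells with at least 500 detected genes and under 10% mitochondrial UMIs were kept. This removed 354 of 9123 cells, 263 of them with too few genes and 115 with too many mitochondrial UMIs, some for both reasons. Doublets were scored with scrublet in scanpy 1.11.5 on the pooled cells, although scoring per library had been planned. It called 0 cells, which means that it had not worked, so no doublets were removed and their share is unknown. For clustering, counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were taken without receptor segments, ribosomal, mitochondrial and sex-linked genes, then 30 principal components, 15 neighbours and Leiden clustering at resolution 0.6 with a fixed seed.

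Clusters were first computed with the approximate neighbour search that is the scanpy default, and then with exact principal components and neighbours, so that results could be repeated exactly. The change was made after the first clusters had been seen, and it moved cells between the Treg-like clusters. The approximate search and 3 other Leiden seeds are therefore among the alternatives. A cluster was named where at least 2 markers of a class, and more than of any other class, stood among its 10 leading genes by fold over all other cells, and at least 3 markers were detected in 10% of its cells. The markers were fixed before the data were examined, but this naming rule was set after the leading genes had been seen, and it left 18.1% of the cells unnamed.

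UMIs were summed over the cells of a class and scaled to CPM, and ratios of CPM are given as log2 ratios. No p-values were computed, because cells are not replicates and each group had 1 library. Levels carry exact Poisson intervals, ratios exact conditional intervals and shares exact Clopper-Pearson intervals, all at 95% and for counting error only. The comparison of effector with other Treg-like cells had been planned within each library and was made on the pooled cells. The comparison of Treg-like with conventional CD4-like cells was chosen after the clusters had been seen, and it was later taken apart by Treg-like cluster, after the values had been seen. Named genes were the 12 highest and 12 lowest log2 ratios among genes with at least 50 CPM in either class and at least 20 UMIs, whose interval left out 0. Receptor segments, ribosomal, mitochondrial and sex-linked genes, predicted genes, cell type markers and the 10 leading genes of the clusters compared were left out. Foxp3, Il2ra and Cd4 are always given. This rule was carried over from the planned comparison of STAg with PBS.

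Gene lists, 37 in all, were fixed before the data were examined. A list's value is the median log2 ratio of members with at least 20 UMIs that had not named or led a cluster. It is given with its percentile among 10000 random lists matched on mean expression in 20 bins. These random lists were not matched on whether a gene was used for clustering, so percentiles can be partly built in. The lists described were chosen after their values had been seen. The value of 1 list member is not reported here. Clusters were built from the UMIs that were then compared, so ratios between clusters are larger than they would be in independent data. An alternative that clustered on a random part of the UMIs and measured on the rest bears on this. Shares of cells with a UMI were taken after thinning each cell to 1036 UMIs, which left out 874 shallower cells and kept 7895. Gene coordinates come from GENCODE M21 on GRCm38, which is the mm10 assembly.

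The interval and list calculations were tested on simulated counts drawn from the real means. For Treg-like against conventional CD4-like cells, with 3395 genes at 50 CPM or more, intervals held the true value for 97% of 100 genes changed by a log2 ratio of 1, 96% of 100 changed by 2 and 94.9% of 3195 unchanged genes. For effector against other Treg-like cells, with 3389 genes, the shares were 99%, 96% and 94.8%. The simulation treats the classes as given and does not cover error in the clusters. It drew Poisson counts, for which the intervals are exact, so coverage near 95% was fixed in advance and tests the calculation only. Spread between cells, mice or libraries beyond Poisson counting is not covered. Alternatives covered scaling (edgeR 4.0.16 TMM, or totals without ribosomal and mitochondrial genes), cell weighting, thinning, cell filters, clustering settings, seeds, the UMI split and the definition of Treg-like cells. The stricter cell filter asked for at least 1000 genes and under 5% mitochondrial UMIs, which left 3067 cells that were clustered and named afresh. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and R 4.3.3.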

Results

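Splenic CD4+CD25+ T cells were isolated from C57BL/6 mice aged 2 months that had received PBS or STAg by intraperitoneal injection, and were profiled by droplet single-cell RNA sequencing. CD4+CD25+ selection enriches regulatory T (Treg) cells, which restrain immune responses. The labels do not spell out STAg or give the number of mice. There were 2 groups, PBS and STAg, with 1 library per group, so neither group had a replicate. The deposited table held 11893 genes and 9123 cells with 16164651 unique molecular identifiers (UMIs) in all. Its cell columns, as analysed here, carried no names, and 0 of them could be mapped to PBS or STAg. The effect of STAg, which the design addresses, was therefore not estimated, and the values that follow describe both libraries pooled as 1 sample. A cluster drawn mostly from 1 library could not be recognised. After filtering, 8769 cells remained, with a median of 1595 UMIs and 954 detected genes per cell. Intervals are exact 95% Poisson or binomial intervals that cover counting error only.

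The cells formed 12 clusters, of which 7 could be named from marker genes. Treg-like cells (clusters 1 and 3) were 53.6% of the kept cells (4704 cells, interval 52.6% to 54.7%). Cluster 3, named effector Treg-like, held 1751 of them, or 37.2% (35.8% to 38.6%). Cluster 1 was named by the leading genes Gpr83, Lrrc32 and Il2ra. The name of cluster 3 rested on 2 leading genes, Maf and S100a4, and no core Treg marker used for naming led it. Its Foxp3 level is given below. Conventional CD4 T-like cells made up 20.1% (1763 cells, 19.3% to 20.96%). Smaller named clusters were proliferating cells at 3.11% (2.76% to 3.50%), interferon-responsive cells at 2.33% (2.02% to 2.66%), NK-like cells at 2.20% (1.90% to 2.53%) and myeloid-like cells at 0.49% (43 cells). The other 5 clusters, with 1589 cells or 18.1% (17.3% to 18.9%), stayed unnamed. Cluster 4, the largest of these with 929 cells, had a median of 963 UMIs per cell, and cluster 6, with 287 cells, had a median of 2687. The CD25 selection, the cell filter and the authors' own filtering can all set these shares. The shares also depended on the clustering. The Treg-like share ranged from 20.3% at Leiden resolution 1.2 to 73.99% with UMIs split between clustering and measuring, and was 30.03% under seed 3. The effector share was 20.7% with the stricter cell filter and 14.9% with split UMIs, or 23.3% with those clusters matched to the main classes. It also depended on the random seed. It was 47.3% and 52.8% under seeds 1 and 2, where 2375 and 2578 cells were named effector. Under seed 3 it was 66.5%, although the effector cells numbered 1752, because the best match of cluster 1, with 2306 cells, was not named Treg-like.

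**Figure D1:**
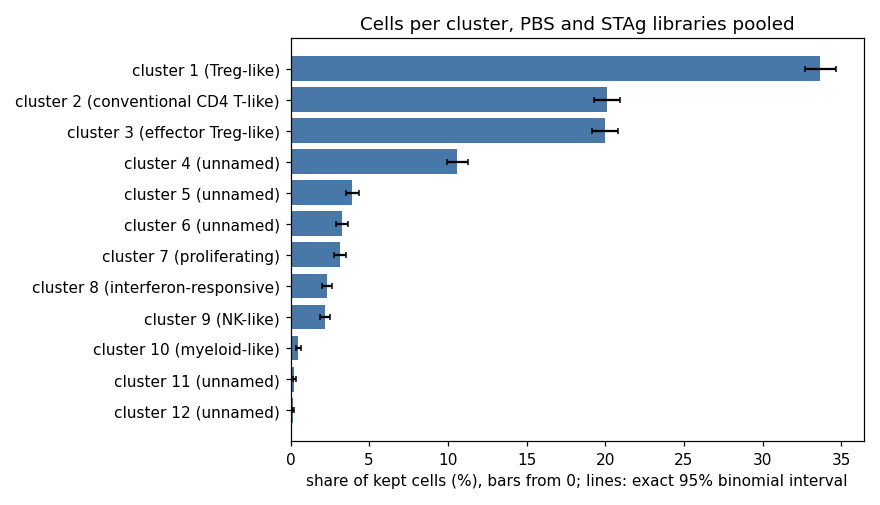
Share of the 8769 kept cells (horizontal axis, percent) in each of the 12 clusters (vertical axis), both libraries pooled, with exact 95% binomial intervals as lines. Clusters 1, 2 and 3 held 33.7%, 20.1% and 19.97% of the cells.

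Foxp3 (ENSMUSG00000039521, GRCm38 chromosome X, 7573644 to 7595245) is the transcription factor that defines the Treg lineage. It was among the markers allowed for naming, but it was not a leading gene of any cluster. Foxp3 was among the genes used to build the clusters, so its distribution describes them and is no independent check. It stood at 301.6 CPM (UMIs scaled to a class total of 1000000) in Treg-like cells (290 to 314) and at 45.4 CPM in conventional CD4-like cells (38.1 to 53.7). With each cell thinned to 1036 UMIs, 26.3% of Treg-like cells (25.03% to 27.6%) had a Foxp3 UMI, against 4.43% of conventional CD4-like cells (3.50% to 5.52%). Without thinning, these shares were 37.5% and 6.86%. NK-like cells, which should lack Foxp3, had a Foxp3 UMI in 6.88% after thinning (3.71% to 11.5%), and the unnamed cluster 5 in 3.25% (1.64% to 5.75%). The share in conventional CD4-like cells lay between these shares, and what it reflects stays open. Median depths were 1611 UMIs in the conventional CD4-like cells and 1832 in the NK-like cells. Il2ra, which encodes CD25 (ENSMUSG00000026770; chromosome 2, 11642807 to 11693193), stood at 311 CPM in Treg-like cells and 32.5 CPM in conventional CD4-like cells. Cd4 (ENSMUSG00000023274; chromosome 6, 124864692 to 124888221) was lower in Treg-like cells, at 214 against 301 CPM, a log2 ratio of -0.49 (-0.61 to -0.37).

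**Figure D2:**
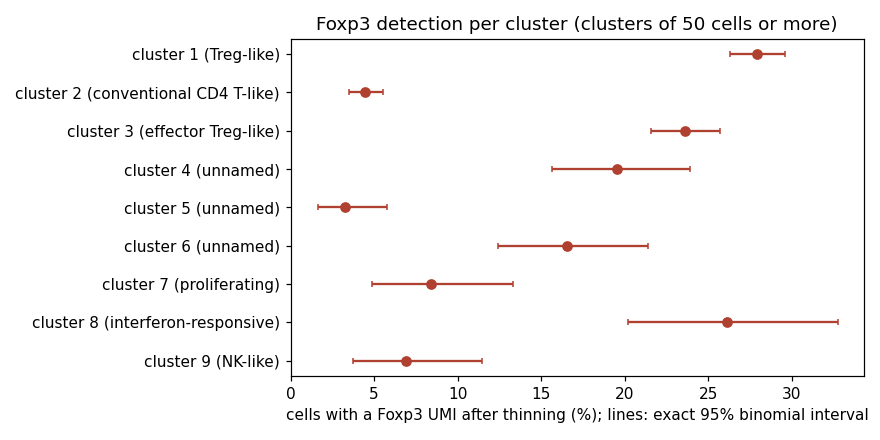
Percent of cells with a Foxp3 UMI after thinning to 1036 UMIs (horizontal axis) in each cluster of 50 or more cells (vertical axis); points are shares and lines exact 95% binomial intervals. Cluster 1 stood at 27.9%, cluster 3 at 23.6%, cluster 2 at 4.43% and the NK-like cluster 9 at 6.88%.

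Treg-like cells were next compared with conventional CD4-like cells in the genes that had not named or led their clusters. Genes of the central and resting list were lower in Treg-like cells for 12 of 14 members (median -0.88 over all members). Dapl1, Igfbp4 and Lef1 of that list also led the conventional CD4-like cluster. The comparison therefore does not tell Treg identity apart from a less resting state. The largest excess in the Treg-like class was that of Penk, which encodes the opioid precursor proenkephalin, at 77.3 against 4.64 CPM (log2 ratio 4.06, 3.30 to 4.94). Most of it lay in the effector cluster: Penk stood at 179 CPM there and at 10.0 CPM in the other Treg-like cells, 602 and 51 UMIs, with log2 ratios of 5.27 and 1.11 over conventional CD4-like cells. The Penk ratio also depended on how the classes were drawn, and its log2 value was 0.23 at Leiden resolution 1.2 (3.94 with clusters matched to the main classes), 0.40 with the stricter cell filter and 0.75 for cells with a Foxp3 UMI against all others. Rgs1, a regulator of G-protein signalling, stood at 397 against 45.7 CPM (log2 ratio 3.12), and Il2rb, the interleukin-2 receptor beta chain, at 312 against 40.8 CPM (log2 ratio 2.94). Gsta4, Serpina3g, Hopx, Cxcr3, Gbp3, Coro2a, Tiam1, Itgb1 and Nt5e, the ectonucleotidase CD73, completed the 12 highest, with log2 ratios of 2.15 to 3.14. Of these, Cxcr3, Serpina3g and Itgb1 were also mostly effector genes, at 0.24, 1.39 and 0.996 in the other Treg-like cells, whereas Rgs1 and Il2rb were at 3.17 and 2.89 there. The lowest was Klrd1, which encodes the receptor chain CD94, at 8.28 against 58.3 CPM (log2 ratio -2.82, -3.24 to -2.41). Rgcc, Als2cl, Sema4a, Ibtk, Atp1b1, Themis, Mettl9, Fam78a, Gramd3, Chd7 and Arl4c were lower by log2 ratios of -1.89 to -1.34. Themis, a T-cell receptor signalling protein, stood at 28.0 against 82.5 CPM.

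Several gene lists differed together between these classes, as medians over members that had not named or led a cluster. Of the NF-kB and TNF list, 15 of 15 members were higher in Treg-like cells (median log2 ratio 0.82), among them Lta at 1.55 and Traf1 at 0.94. Interferon-gamma-inducible GTPases and their regulators were higher for 16 of 18 members (median 0.54), with Gbp3 at 2.39 and Iigp1 at 1.24. MHC class I and antigen-processing genes were higher for 17 of 18 (median 0.30), with H2-Q6 at 1.53 and Psmb8 at 0.39. IL-2 and STAT5 genes were higher for 11 of 13 (median 0.55), with Il2rb at 2.94 and Cish at 1.91. Type 1 helper genes were higher for 11 of 12 (median 1.30), with Hopx at 2.57 and Cxcr3 at 2.47. Homing and migration genes were higher for 16 of 20 (median 1.12), with Itgb1 at 2.16 and Cd44 at 1.30. Apoptosis regulators were higher for 19 of 22 (median 0.39), with Bcl2a1b at 1.78. T-cell receptor complex genes were lower for 8 of 10 (median -0.17). Nuclear oxidative phosphorylation genes showed little difference, with a median of 0.03 over 33 members. Among 10000 random lists of matched expression, the lists from NF-kB to homing lay at percentile 100 and apoptosis at 99.98. The receptor complex lay at 1.19 and oxidative phosphorylation at 84.6. The random lists were not matched on use in clustering. Members such as Lta, Traf1, Gbp3 and Iigp1 had been used to build the clusters, so a high percentile can be partly built in. Over all members, including those that named or led clusters, the homing median was 0.67 (17 of 24 higher, with Ccr7 at -1.24) and the IL-2 and STAT5 median 0.95 (13 of 15 higher). The type 1 helper and homing values were carried mostly by the effector cluster, whose medians over conventional CD4-like cells were 2.06 and 1.27. In the other Treg-like cells the medians were 0.24 (7 of 9 higher, percentile 95.3) and 0.22 (15 of 19 higher, percentile 99.7). NF-kB and TNF, the GTPases, MHC class I and IL-2 and STAT5 were higher in the other Treg-like cells too, at 0.59, 0.55, 0.22 and 0.68. The receptor complex was lower in those alone, at -0.27 against 0.05 in effector cells. Apoptosis regulators were higher in both, at 0.34 in the other Treg-like and 0.28 in effector cells. Bcl2a1b was mostly an effector gene, at 301 CPM there, 67.1 CPM in the other Treg-like and 46.4 CPM in conventional CD4-like cells. Markers of some other cell types moved the same way. Their values are over all members and carry no percentile, because too few members remained without the naming markers. B-cell markers were higher in Treg-like cells for 6 of 6 members (median 0.72, with Cd74 at 135 against 43.1 CPM). Myeloid markers were higher for 7 of 8 (median 0.27), while NK markers showed little difference, with 4 of 7 higher (median 0.09). No test across mice was possible, and the clusters were built from the UMIs that were compared. Cells with a Foxp3 UMI were also set against all other cells, which is a different reference from the conventional CD4-like class. Those other cells held most NK-like cells, whose type 1 helper median over all other kept cells was 3.51. They also held cells of the unnamed clusters and most Treg-like cells, of which 37.5% had a Foxp3 UMI without thinning. In this split the type 1 helper median was -0.81 and the homing median -0.14, with Cxcr3 at -0.29 and Itgb1 at -0.18. These values therefore do not compare Treg-like with conventional CD4-like cells. The other medians were smaller in that split: 0.23 for NF-kB and TNF, 0.15 for the GTPases, 0.10 for MHC class I, 0.18 for IL-2 and STAT5, 0.14 for apoptosis and -0.047 for the receptor complex.

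Effector Treg-like cells were then compared with the other Treg-like cells, by the same rule. The central and resting list was lower in effector cells for 12 of 14 members (median -1.20 over all members). Ccl1, a chemokine that binds CCR8, showed the largest excess in effector cells, at 57.8 against 1.77 CPM (log2 ratio 5.03, 4.08 to 6.18). Penk stood at 179 against 10.0 CPM (4.16, 3.75 to 4.61) and Cxcr3, a chemokine receptor of type 1 responses, at 181 against 17.7 CPM (3.35, 3.03 to 3.69). Serpina3g, Glrx, Casp1, Mmd, S100a11, Bcl2a1b, Tnfsf11, Cdkn2c and Rilpl2 were higher by log2 ratios of 2.05 to 2.73. Tubb2a was the lowest, at 19.1 against 68.7 CPM (-1.85, -2.26 to -1.46). St8sia6, Ms4a4c, Treml2, Ctsw, Txk, Slc17a9, Aven, Bcl2, Lmo4, Hmgcs1 and Rasgrp2 followed at -1.77 to -1.26. The survival gene Bcl2 stood at 347 against 898 CPM, while its relative Bcl2a1b stood at 301 against 67.1 CPM. Foxp3 was close between these clusters, at 278 and 317 CPM (log2 ratio -0.19, -0.31 to -0.07), and Il2ra was lower in effector cells, at 228 against 365 CPM (-0.68). Cd4 was higher, at 271 against 177 CPM (0.61). Where the classes were drawn otherwise, some of these directions turned. The best match of cluster 3 held 82.2%, 59.0% and 94.4% of its cells under seeds 1, 2 and 3. With split UMIs, 58.6% of cluster 3 lay in a cluster of 3192 cells that was also the best match of cluster 1. When matched, that cluster was the reference, against an effector class of 968 cells. The split values therefore do not compare the same classes as the main setting. At Leiden resolution 1.2, where most Treg-like subclusters had no name, Ccl1 was at -0.51 and Penk at -0.73, but they were at 5.33 and 4.26 when clusters were matched to the main classes. Ccl1 was also at 0.44 with UMIs split between clustering and measuring, at -0.30 with split UMIs matched and at 0.23 with the stricter cell filter. Penk was at 2.90 and 2.33 in those split settings. With the stricter cell filter Penk was at -0.89 and Lmo4 at 2.05. That filter left 293 cells named effector, and no matched version of it was run. A change in which cluster took the name is therefore not told apart there. With split UMIs Hmgcs1 was at 0.49 and Cd4 at -0.050.

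Treg suppression genes, type 1 helper genes and follicular helper genes were higher in effector cells for 8 of 8, 12 of 12 and 6 of 6 members, with medians of 2.33, 1.49 and 1.17. Examples were Nt5e at 1.34, Cxcr3 at 3.35 and the follicular receptor Cxcr5 at 1.92. These 3 medians kept their sign under all 18 settings tried, but the suppression median ranged down to 0.13 with the stricter cell filter. Over all members, including those that named or led clusters, 12 of 13, 14 of 15 and 8 of 8 were higher. Those medians were 3.11, 1.56 and 1.56. The NF-kB and TNF list had 11 of 15 members higher (median 0.29), with Relb at 0.90. That median was -0.15 at Leiden resolution 1.2 (0.34 when matched), -0.03 with the stricter filter and -0.04 when the UMIs were split and clusters matched. IL-2 and STAT5 genes were lower for 10 of 13 (median -0.21), with Pim1 at -0.52. Interferon-gamma-inducible GTPases had 12 of 18 members higher and a median of 0.15, which took either sign across settings. Cholesterol synthesis genes were lower for 13 of 14 (median -0.85), with Fdps at -0.90 and Msmo1 at -0.93. Ribosome biogenesis genes were lower for 17 of 18 (median -0.37), with Srm at -0.98 and Myc at -0.97. Among random lists, again matched on expression alone, the first 3 lists lay at percentile 100. NF-kB and TNF lay at 99.93, the GTPases at 95.4, IL-2 and STAT5 at 0.41, and cholesterol synthesis and ribosome biogenesis at 0. Those last 2 lists did not hold their direction. With UMIs split at random between clustering and measuring, the cholesterol median was 0.30 and the ribosome biogenesis median 0.87. In that setting most of cluster 3 lay outside the effector class. The ribosome biogenesis median was also 0.54 at resolution 0.3, 0.53 without a cell filter and 0.44 with another seed.

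**Figure D3:**
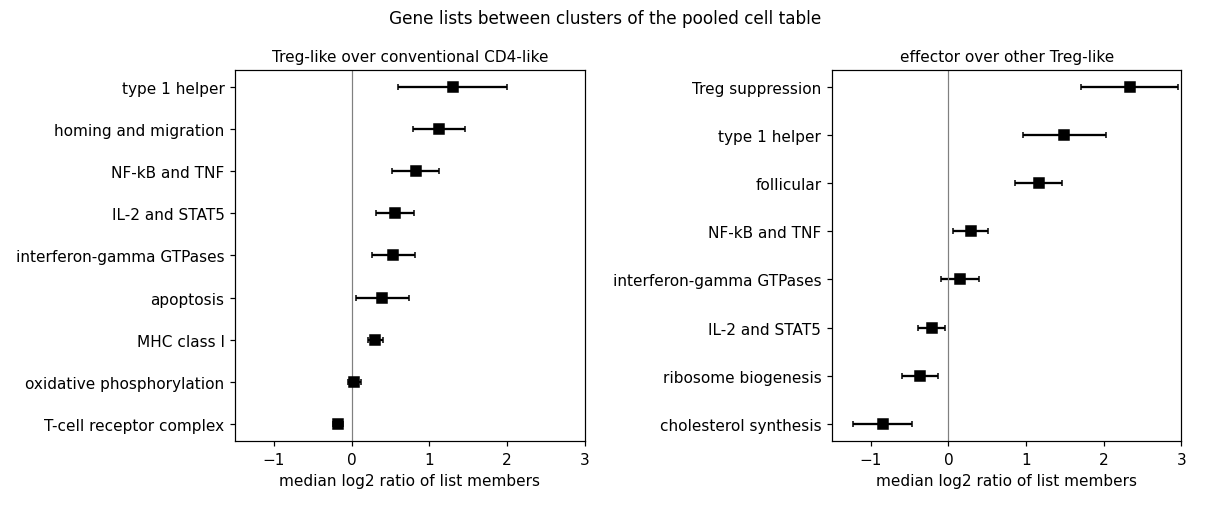
Median log2 ratio of gene list members (horizontal axis) for Treg-like over conventional CD4-like cells (left) and effector over other Treg-like cells (right), both libraries pooled. Squares are medians and lines extend by the typical half-width of a member's counting interval; the NF-kB and TNF list stood at 0.82 on the left and 0.29 on the right.

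Proliferation genes were seen in most cells at low level. After thinning, 85.1% of cells (84.3% to 85.9%) had at least 2 UMIs over the proliferation list, the threshold set in advance, and 49.0% had at least 4, so this threshold separated few cells. At 4 UMIs the share was 49.8% in Treg-like cells (48.3% to 51.2%), 39.6% in conventional CD4-like cells (37.2% to 42.0%) and 100% in the proliferating cluster, whose leading genes it contains. It was 70.4% in cluster 6 (64.7% to 75.7%), 66.7% in NK-like cells (59.5% to 73.3%) and 27.5% in cluster 5 (22.8% to 32.6%). The gap between Treg-like and conventional CD4-like cells was not shared by the list, whose median log2 ratio was 0.14 with 11 of 19 members higher. Among its members, H2afz stood at 1630 against 705 CPM, while Tuba1b was at -0.33 and Stmn1 at -1.95, so the gap was not taken as one in dividing cells.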

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

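Among the tests in this part, both mixture tests, the test for dividing cells and the test of free Foxp3 RNA were chosen only after related values had been seen. The depth-matched tests were set before their values were seen. The comparison of Foxp3 between the NK-like cluster and cluster 5 was also added after both values had been seen. Cells were not assigned to groups, so no effect of STAg was tested for any pattern, and dividing cells were the only biological explanation tested.

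Haemoglobin RNA was outside the main measurement and stood above the 3 counts that a count of 0 allows. Hba-a1, Hba-a2 and Hbb-bt had 56 UMIs together, while Hbb-bs had 0. Y-linked genes, which were left out of clustering and ranking, had a UMI in 3158 cells, or 34.6% of all cells, also above that limit. They were Ddx3y, Eif2s3y, Kdm5d and Uty, with 4235 UMIs together.

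Cluster 4 stood apart by Actb, at 44865 CPM against 8418 CPM in Treg-like cells and 32277 CPM in the proliferating cluster 7, and by genes such as Pdcd4, Abhd2 and Slc39a1, in shallow cells. Cluster 7 was also the next highest for these 3 genes, with Pdcd4 at 1135 against 411 CPM. Shallow depth was tested within the cluster's interquartile range of UMIs. There, 72 such genes had a median log2 ratio of 1.80 over clusters 1 to 3, where 0.5 had been set as the bound. These genes were chosen for being higher in cluster 4 than in all other kept cells, and the clusters were built from the same UMIs. The test could therefore hardly have given a low value, and shallow depth as the whole cause stays open. The depths still differed within that range, with medians of 963 and 1135 UMIs. RNA from the other cells of the table stays open. Of the 72 genes, 37.5% were higher than in each other cluster, between the bounds of 10% and 50% set for that test. Markers of another cell type moved with the pattern: against all other cells, 8 of 8 B-cell list members were higher in cluster 4 (median log2 ratio 2.78, percentile 100). Of these, Cd74, H2-Aa, H2-Ab1 and H2-Eb1 are among the 72 genes, and each stood higher still in cluster 12.

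Cluster 6 stood apart by biosynthesis genes such as Srm, Mettl1 and Nop56, in deep cells. Greater depth as the whole cause stays open. The test used 443 genes chosen for being higher in cluster 6 than in all other kept cells, so it could hardly have given a low value. Their median log2 ratio was 1.21 against cells of clusters 1 to 3 in the same range of UMIs. Here too the depths still differed within that range, with medians of 2687 and 2270 UMIs. Dividing cells stay open too. The proliferation list had a median of 0.75 over clusters 1 to 3, against 4.47 in the proliferating cluster, so cluster 6 was far from that level. The proliferating cluster was named from members of this list, which sets a high bar, and the bound was chosen after related values had been seen. The test therefore does not decide. Of cluster 6, 70.4% had at least 4 UMIs of that list after thinning, against 49.8% of Treg-like cells. Doublets stay open, because 48.5% of the 443 genes were higher than in each other cluster, just under the bound of 50%, and no doublet caller worked. The cluster was also unstable: the best-matching clusters under 3 other seeds held 86.4%, 58.9% and 80.5% of its cells.

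Foxp3 UMIs were found in the NK-like cluster, at 63.5 CPM. Free RNA from Treg-like cells stays open. Of Foxp3, Ctla4, Nrp1, Gpr83, Lrrc32 and Ikzf4, 0 had an interval that left out the pooled ratio, 18.6% of the Treg-like level. With 26 or fewer UMIs per gene, the test could only have found large departures. Against free RNA spread evenly over cells, Foxp3 stood higher in the NK-like cells than in cluster 5, at 63.5 against 30.4 CPM (log2 ratio 1.06, 0.20 to 1.92). The libraries were pooled, so a difference in free RNA between them is not excluded. Doublets of NK-like and Treg-like cells would keep the same ratio and were not told apart from free RNA by this test.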

How the results depend on the processing

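No paired analysis was possible because no cell could be assigned to a sample. The settings tried on the share of cells with a UMI and on the proliferation threshold, as well as resolutions 0.3 and 1.2 and the unfiltered table for shares of classes, were set before the data were examined; all others were added later. The other settings foreseen for STAg against PBS were not run. Removing no doublets equals the main setting, because 0 were called. The change of variable genes foreseen was run only without the interferon lists. "Matched" means that a cluster took the class that most of its cells had in the main clustering. The stricter filter was not run matched. A split of UMIs also lowers the depth of each part and changed which cells made up the classes. Its effect therefore mixes depth and changed classes with circularity. The cause of each difference was not tested, unless the setting itself shows it. Some settings gave no named cluster for a class, so they have no value for it: conventional CD4-like cells with unmatched split UMIs, interferon-responsive cells at resolution 0.3, unfiltered and without interferon lists, and proliferating cells at unmatched resolutions 0.3 and 1.2 and with the stricter filter.

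Shares of classes depended on the clustering. The share of Treg-like cells, 53.6% in the main setting, was 60.3% at resolution 0.3, matched or not. At resolution 1.2 it was 20.3%, where most subclusters had no name, and 54.9% when matched. It was 58.3% unfiltered, 46.1% with the stricter filter and 56.8% without interferon lists. Split UMIs gave 73.99%, or 47.4% matched. Approximate neighbours gave 55.6%, and seeds 1, 2 and 3 gave 57.2%, 55.6% and 30.03%. Effector cells were 37.2% of Treg-like cells in the main setting and 33.7% at resolution 0.3. At resolution 1.2 they were 32.2%, or 38.98% matched. They were 35.1% unfiltered, 20.7% with the stricter filter and 35.2% without interferon lists. Split UMIs gave 14.9%, or 23.3% matched. Approximate neighbours gave 40.8%, and the 3 seeds 47.3%, 52.8% and 66.5%. Seed 3 named 1752 effector cells, against 1751 in the main setting, and 94.4% of cluster 3 lay in its best match. Its share rose because the Treg-like cells fell from 4704 to 2633, when the best match of cluster 1, with 2306 cells, was not named Treg-like. Other values for seed 3 rest on the same smaller class. Cluster 3 was itself unstable: its best match held 82.2% and 59.0% of its cells under seeds 1 and 2, and 58.6% with split UMIs. The match with split UMIs, a cluster of 3192 cells, was also the best match of cluster 1. It formed the other Treg-like class when matched, so most of cluster 3 then lay in the reference.

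Conventional CD4-like cells, 20.1% in the main setting, were 17.8% at resolution 1.2, 18.3% unfiltered and 16.5% with the stricter filter. They were 26.5% with split UMIs matched and 19.1% with seed 3. Interferon-responsive cells, 2.33%, were 3.20% at resolution 1.2 and 1.40% with the stricter filter. Approximate neighbours and seed 1 gave 1.57%, seed 2 gave 1.61% and seed 3 gave 1.41%. NK-like cells, 2.20%, were 1.72% at resolution 1.2 and 2.70% when matched. They were 1.45% unfiltered, 2.64% with the stricter filter, 1.55% without interferon lists and 1.06% with split UMIs. Proliferating cells, 3.11%, were 2.63% with split UMIs. A Foxp3 UMI was seen in 26.3% of Treg-like cells when thinned, in 37.5% unthinned, and 5.11% had at least 2 UMIs. In conventional CD4-like cells the shares were 4.43%, 6.86% and 0.236%. At least 2 UMIs of the proliferation list were seen in 85.1% of cells, and at least 4 in 49.0%.

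For Treg-like over conventional CD4-like cells, 27 genes under 17 settings gave 458 values, of which 378 lay within the main counting interval, 78 moved in size and 2 changed sign. The 2 were Cxcr3 at -0.29 and Itgb1 at -0.18, when cells with a Foxp3 UMI were set against all other cells. Penk, at 4.06 in the main setting, moved most among the sizes: 0.23 at resolution 1.2 (3.94 matched), 0.40 with the stricter filter and 0.75 with the Foxp3 UMI split. That split also reduced the log2 ratios of the other genes. Those other cells held most NK-like cells, most of cluster 5 and most Treg-like cells. Of 162 list medians, 146 stayed within the typical counting interval. With cells split by a Foxp3 UMI, the medians were -0.81 for type 1 helper genes, -0.14 for homing, 0.23 for NF-kB and TNF and 0.15 for interferon-gamma-inducible GTPases. They were 0.10 for MHC class I, -0.047 for the T-cell receptor complex and 0.18 for IL-2 and STAT5. The GTPase median was also 0.87 at resolution 1.2 and 0.82 with seed 3, and the IL-2 and STAT5 median 0.96 at resolution 1.2. With split UMIs matched, MHC class I stood at 0.16 and the receptor complex at -0.090, the latter also at -0.098 with seed 3. Oxidative phosphorylation stood at 0.13, both at resolution 0.3 and with seed 1.

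For effector over other Treg-like cells, 459 values of 27 genes held 274 within the counting interval, 177 that moved in size and 8 that changed sign. Ccl1 was at -0.51 at resolution 1.2 (5.33 matched), -0.30 with split UMIs matched, 0.44 unmatched and 0.23 with the stricter filter. Penk was at -0.73 at resolution 1.2 (4.26 matched) and -0.89 with the stricter filter, where Lmo4 was at 2.05. Split UMIs lowered Penk from 4.16 to 2.90, or 2.33 matched. Hmgcs1 was at 0.49 with split UMIs and 0.74 matched, and Cd4 at -0.050 with split UMIs. Of 144 list medians, 107 stayed within the typical counting interval. The suppression median, 2.33, was 1.19 thinned, 1.45 with members of at least 100 UMIs, 0.94 at resolution 1.2 and 1.59 matched. It was 0.13 with the stricter filter, 0.98 with split UMIs, 0.50 matched, and 1.49 with seeds 2 and 3. Type 1 helper genes, 1.49, were at 0.93 with split UMIs, matched or not. Follicular genes, 1.17, were at 0.75 with the stricter filter and 0.53 with split UMIs matched.

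The NF-kB and TNF median, 0.29, was -0.15 at resolution 1.2 (0.34 matched), -0.032 with the stricter filter and -0.043 with split UMIs matched. Cholesterol synthesis, -0.85, was at -0.43 at resolution 0.3, -0.39 unfiltered, 0.30 with split UMIs and 0.24 matched. Ribosome biogenesis, -0.37, was at 0.54 at resolution 0.3, 0.53 unfiltered, 0.87 with split UMIs, 0.85 matched and 0.44 with seed 1. IL-2 and STAT5 genes, -0.21, were at -0.41 with seed 3. Interferon-gamma-inducible GTPases, 0.15, were at -0.30 at resolution 0.3, -0.14 at resolution 1.2, -0.33 unfiltered and -0.13 with the stricter filter. Split UMIs gave -0.36, or -0.47 matched, and seeds 2 and 3 gave 0.41 and -0.58. TMM scaling shifted all log2 ratios by -0.016 in the first comparison and -0.059 in the second.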

Other observations

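All comparisons in this part were chosen after the clusters had been seen, and each sets a cluster against all other kept cells, without the cluster's 10 leading genes. Cluster 5, unnamed and led by genes that include Cxcr6 and Il4, held 342 cells, or 3.90%. Type 1 helper genes were higher there for 14 of 15 members (median log2 ratio 2.64, against 3.51 in the NK-like cluster), while the core Treg list was lower for 13 of 16 (median -2.03, against -2.88 in conventional CD4-like cells). Foxp3 stood at 30.4 CPM in cluster 5, below the NK-like level of 63.5 CPM, Il4 at 214 CPM and Tbx21 at 119 CPM. Il2ra, the CD25 gene, stood at 92.6 CPM in cluster 5 and 95.3 CPM in the NK-like cells, against 32.5 CPM in conventional CD4-like cells.

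Interferon-responsive cells, cluster 8, had MHC class I and antigen-processing genes higher for 16 of 18 members (median 0.45), against medians of 0.24 in cluster 5 and 0.22 in cluster 3. Foxp3 stood at 257 CPM in them, and 26.1% had a Foxp3 UMI after thinning (20.2% to 32.7%), close to the Treg-like share of 26.3%. Whether these cells came from PBS or STAg mice cannot be read from the table as used here. Cluster 8 was unstable too: its best match held 66.2%, 67.6% and 60.3% of its cells under seeds 1, 2 and 3. With split UMIs that share was 56.4%. In the proliferating cluster 7, nuclear oxidative phosphorylation genes were higher for 32 of 33 members (median 0.58) and NF-kB and TNF genes lower for 17 of 17 (median -0.97). Cluster 6 had a median of 0.41 for the former list, and conventional CD4-like cells one of -0.66 for the latter.

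Cluster 6 combined higher T-cell activation genes, 13 of 13 (median 1.29), with higher heat shock and chaperone genes, 15 of 17 (median 1.14, against 0.57 in cluster 7). Foxp3 stood at 145 CPM and Cd4 at 131 CPM in it. Cluster 10, the 43 myeloid-like cells, held Cd3e at 736 CPM (548 to 968) and Foxp3 at 144 CPM (69.2 to 266) beside C1qa at 1357 CPM, with a median of 1465 UMIs per cell.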
